A study of Arabidopsis thaliana with 24 samples.

How the data were processed

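The labels describe whole seedlings of Col-0 and IP-Svi-0 grown at 10, 16, 23 and 27 °C, with 3 libraries for each of 8 groups, made with a strand-specific kit. Per the labels, the authors checked reads with FastQC, aligned them with HISAT2 to the Col-0 genome (TAIR10), counted them with HTSeq and used Cufflinks and Cuffdiff, with versions not given in the sources used here. The deposited table holds counts: raw read counts for 33602 genes in 24 libraries, with 5 further lines for reads not assigned to a gene. All 24 libraries were used. The strand setting of the counting step is not given in the sources used here, and the counts lie mostly at genes with an exon on the other strand, so counts at a gene may come from the opposite strand. Gene positions, biotypes and overlaps were read from the RefSeq table of TAIR10.1, in which 32835 gene IDs were matched and 767 were not. Of the IDs, 279 were organelle genes.

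Counts were scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr with the 8 groups and a minimum count of 10, which left 10097. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, and the common biological coefficient of variation was 0.225 with 22 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Comparisons were the accessions at each temperature and over all 4, each temperature against 23 °C in each accession, the interaction at each temperature, and the 3 interaction terms together. Standard errors were computed as the log2 change over the root of its F statistic. Temperature cannot be separated from age, and all comparisons within an accession share its 23 °C libraries. Library r in 1 group was not treated as paired with library r in another.

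The rule for naming genes was fixed before the data were examined. It named 16 flowering genes whether called or not, the largest changes of each comparison, and up to 2 called members of each list in each direction. Genes without a symbol are given by ID. The gene with the most counts (AT1G72600) was chosen after its values were seen. Lists of genes were fixed at the same time, 17 in all, of which 15 had enough measured genes for a set test. Sets were tested with camera, which compares the genes of a list with all other genes, at a preset correlation between genes, and adjusted within the genotype, temperature and interaction comparisons. Camera was repeated with a correlation estimated from each list. Sets were also tested with fry, whose first p asks whether the genes of a list move on balance in 1 direction and whose mixed p asks whether they move in either direction. Neither compares them with other genes. Adjusted over the list alone means that the p values of the list's genes were adjusted among themselves. Genes with a mean under 0.05 CPM in 1 accession and at least 1 CPM in the other were counted without a test.

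Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors, the replicate number as a block, 2 groups alone, no expression filter, a minimum of 1 CPM, a fold threshold of 2, and each library left out in turn. Chosen after the data were seen were a fit with the share of nuclear counts at genes without an overlap as a covariate, libraries thinned to 338784 counts, organelle genes left out, and separate fits of genes with and without an overlap. Scaling by DESeq2 size factors shifted no comparison by more than 0.0355 on the log2 scale upward or -0.0321 downward. Expected overlaps between 2 lists of called genes were the products of their sizes over the tested genes. Where a group had no count, a fold was given as at least the ratio to a floor of 3 counts over the group, and with 1 to 3 counts no fold was given. Differences between responses are printed as fitted also where a group had no count. Intervals and floors cover counting error only.

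The fit was tested on simulated data with the counts and dispersions of this series. For the accessions at 10 °C, 18.2% of genes changed 2-fold and 82.2% changed 4-fold were called, and 6.12% of the calls were false. For IP-Svi-0 at 27 against 23 °C the values were 14.8, 82.2 and 4.95%, and for the interaction at 16 °C 2.08, 40.4 and 4.76%. In these 3 simulated comparisons most 2-fold changes were therefore missed. Depth was not varied, so the loss cannot be assigned to depth alone. The simulated comparison at 10 °C had 98 calls and the real one 2422. The adjusted p is easier to pass where more genes differ, so recovery in the real data can be higher. Apart from the planted changes, all groups were drawn from 1 mean and 1 dispersion per gene. Differences between libraries such as the share used as covariate were not simulated, so the share of false calls in the real data can differ. Camera called 1 of 1 planted list and 0 of 19 random lists. The simulated genes were drawn independently, so this did not test the effect of correlation between the genes of a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, transcript models and values from Cufflinks were not analysed here.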

Results

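RNA was sequenced from whole seedlings of 2 accessions of Arabidopsis thaliana with strand-specific libraries. Col-0 is the reference accession, and IP-Svi-0 is a natural accession that flowers early according to the labels. Each of the 8 combinations of accession and temperature (10, 16, 23 or 27 °C) had 3 libraries, 24 in all. Seedlings were collected 23 days after transfer at 10 °C, 12 days at 16 °C, 8 days at 23 °C and 7 days at 27 °C, so age changed together with temperature. The labels do not say whether replicates were separate cultures. The series asked which genes differ between the accessions and which of them take part in early flowering.

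Each library held 22215651 to 24308874 reads, of which 1.41 to 3.61% were counted at annotated genes. The counts at genes came to 338784 to 870567 per library. In Col-0 the libraries held 355824 to 630185 at 10 °C, 338784 to 381485 at 16 °C, 558395 to 748770 at 23 °C and 511199 to 745270 at 27 °C. In IP-Svi-0 they held 587720 to 870567 at 10 °C, 560025 to 757211 at 16 °C, 466105 to 508848 at 23 °C and 535141 to 799066 at 27 °C. Reads that the counting step assigned to no gene made up 59.6 to 89.8% of a library. These can include reads that lie at a gene but on the strand not counted. Of 33602 genes in the table, 24758 had a count and 10097 had enough counts to be tested.

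**Figure D1:**
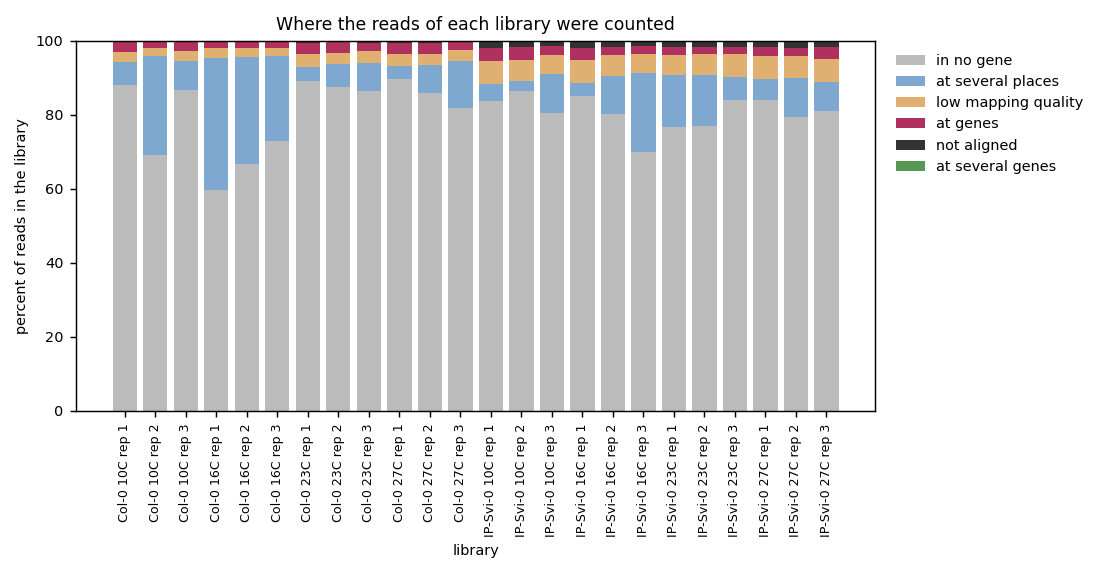
Percent of the reads of each library (vertical axis) counted at genes, assigned to no gene, or set aside, for the 24 libraries. Counts at genes made up 1.41 to 3.61% and reads assigned to no gene 59.6 to 89.8%.

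The counts were not spread evenly over the annotation. Genes with an exon that overlaps an exon on the other strand were 20.5% of the matched nuclear genes and held 54.2% of the nuclear counts. Among protein-coding genes, the median count per kb was 3.39 times higher with such an overlap than without (bootstrap 95% interval 3.17 to 3.61, 6302 against 20410 genes). The gene with the most counts, AT1G72600, lies opposite GER1, an enzyme of fucose synthesis, over 1626 bp of exon. All values below are therefore counts placed at a gene, scaled to library size (CPM), which may come from the other strand, and an overlapping gene is named where a gene first appears.

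**Figure D2:**
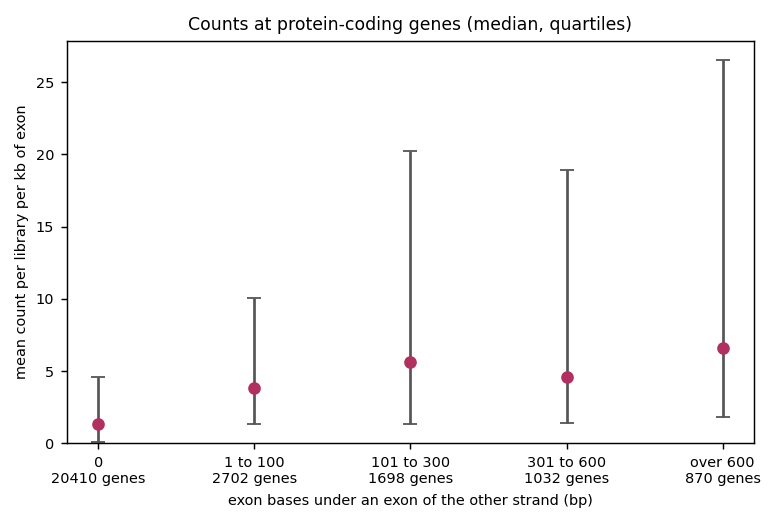
Median counts per kb of exon (vertical axis) of protein-coding genes, grouped by the length of exon that overlaps an exon on the other strand (bp, horizontal axis), with bars for the quartiles. The median was 1.35 without an overlap and 6.59 in the group with the longest overlap.

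The share of nuclear counts at genes without such an overlap differed between groups. At 10 °C it was 39.1 ± 4.35% in Col-0 and 48.6 ± 4.69% in IP-Svi-0 (SD, n = 3 each), and at 16 °C 40.8 ± 6.05% and 48.4 ± 2.37%. At 23 °C it was 45.4 ± 3.23% and 43.2 ± 1.48%, and at 27 °C 45.6 ± 3.89% and 47.0 ± 5.33%. This share is the covariate named below. The first principal component, with 35.2% of the variance, had all Col-0 libraries on one side of 0 and all IP-Svi-0 libraries on the other, and the second, with 14.1%, followed temperature.

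The comparison of the accessions over all temperatures asked which genes differ on average. It tested the mean of the differences at the 4 temperatures. A gene can therefore be called without a difference at each of them. Counts at SOC1 (AT2G45660), a MADS-box promoter of flowering, were higher in IP-Svi-0, with 19.03 ± 12.0 against 3.99 ± 3.30 CPM in Col-0 (SD, n = 12 each; log2 difference 2.18, SE 0.33, adjusted p = 2.1e-06). Counts at FLC (AT5G10140), a MADS-box repressor of flowering, were also higher in IP-Svi-0, with 15.9 ± 4.97 against 5.02 ± 5.54 CPM (log2 difference 1.72, SE 0.34, adjusted p = 0.000109). FLC shares 804 bp of exon with AT5G01675 on the other strand. The counts were few, 149 in IP-Svi-0 and 23 in Col-0 at SOC1, and 116 and 27 at FLC. In Col-0, 2 libraries had no count at SOC1 and 3 had none at FLC. FLM (AT1G77080), a repressor that acts with temperature, was lower in IP-Svi-0, with 7.78 ± 4.26 against 22.4 ± 16.2 CPM (log2 difference -1.38, SE 0.29, adjusted p = 0.000232), and so was its relative MAF2 (log2 difference -0.58, SE 0.19, adjusted p = 0.0152). SVP, the partner of FLM in repression (log2 difference 0.07, SE 0.15, adjusted p = 0.749), and MAF4 (log2 difference 0.17, SE 0.28, adjusted p = 0.687) did not pass the test. On TAIR10.1, SOC1 lies on chromosome 2 from 18807505 to 18811125, FLC on chromosome 5 from 3173382 to 3179448, and FLM on chromosome 1 from 28955483 to 28960234. All 3 are annotated as protein-coding.

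Other flowering genes did not pass the filter on counts and were not tested. FT, which encodes the mobile signal of flowering, had 22 counts over the 12 libraries of IP-Svi-0 and 7 over those of Col-0, and its relative TSF had 7 and 3. CO, which activates FT and shares 743 bp of exon with AT5G15843, had 78 in IP-Svi-0 and 67 in Col-0, and the clock gene GI had 58 and 35. In the same order FRI, which shares 212 bp with AT4G03675, had 46 and 25. MAF3 had 70 and 55, MAF5 12 and 30, FUL 2 and 1, and LFY 4 and 1. AP1 had 0 in both, where 3 counts over the 12 libraries would have been 0.39 CPM in IP-Svi-0 and 0.48 CPM in Col-0.

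**Figure D3:**
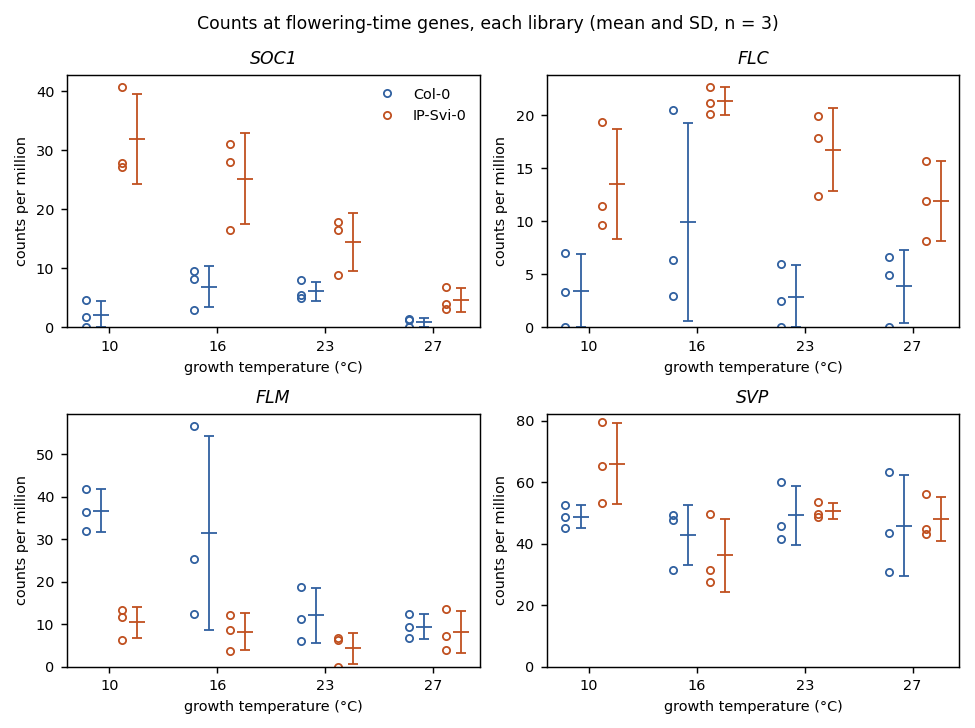
CPM (vertical axis) at SOC1, FLC, FLM and SVP in both accessions at 10, 16, 23 and 27 °C (horizontal axis); open circles are libraries, dashes and bars the mean and SD of 3 libraries, the lower bar cut at 0. Over all temperatures SOC1 had 19.03 CPM in IP-Svi-0 and 3.99 CPM in Col-0.

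Among other regulators of flowering, FRL2, a relative of FRIGIDA, was lower in IP-Svi-0, with 5.58 ± 3.77 against 38.4 ± 15.5 CPM (log2 difference -2.90, SE 0.27, adjusted p = 3.12e-11). CDF3, a factor of the family that represses CO, was lower (log2 difference -2.14, SE 0.16, adjusted p = 3.81e-14), and so was VRN2, a Polycomb protein of vernalization (log2 difference -2.19, SE 0.31, adjusted p = 5.44e-07). SNZ, an AP2-like repressor, was higher (log2 difference 0.98, SE 0.31, adjusted p = 0.0126). Of 16 measured flowering repressors, 2 were higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.491). Their median log2 difference was 0.05 and their mean -0.22. Only 2 of 22 floral integrators, SOC1 and SPL3 (opposite AT2G33815), and 0 of 7 floral organ identity genes had enough counts, the latter with 54 counts in Col-0 and 39 in IP-Svi-0. Glucosinolate genes held some of the largest differences. ESP (AT1G54040), which turns glucosinolate breakdown toward nitriles, had 3936 ± 938 CPM in IP-Svi-0 and 82.4 ± 153 CPM in Col-0 (log2 difference 6.08, SE 0.32, adjusted p = 8.72e-19). At ESP, Col-0 16 °C replicate 3 had 566 CPM and the other 11 Col-0 libraries 20.9 to 59.5, and without that library the difference was 6.70. AOP2 (AT4G03060), a dioxygenase of alkenyl glucosinolate synthesis annotated as a transcribed pseudogene in Col-0, had 333 ± 130.1 against 10.0 ± 6.02 CPM (log2 difference 4.99, SE 0.19, adjusted p = 7.39e-23).

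ESM1, which opposes nitrile formation, was lower in IP-Svi-0 (log2 difference -1.19, SE 0.13, adjusted p = 2.58e-09). Of 25 glucosinolate genes, 9 were higher and 4 lower, or 9 and 6 when adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.248 with an estimated correlation). ESP lies on chromosome 1 from 20170715 to 20173949 and AOP2 on chromosome 4 from 1351688 to 1354096. Genes of cold response had fewer counts in IP-Svi-0. KIN2, a small protein induced by cold, had a log2 difference of -2.80, SE 0.17, adjusted p = 1.72e-16, and COR15A, which protects chloroplast membranes in the cold, a log2 difference of -2.75, SE 0.27, adjusted p = 6.79e-11. Of 19 cold response genes, 2 were higher and 11 lower, or 2 and 14 when adjusted over the list alone (camera adjusted p = 0.000462). Of 13 flavonoid and anthocyanin genes, 0 were higher and 7 lower, or 0 and 9 when adjusted over the list alone (camera adjusted p = 0.000368; adjusted p = 0.0791 with an estimated correlation). They included UGT79B1, an anthocyanin glycosyltransferase (log2 difference -5.29, SE 0.36, adjusted p = 6.87e-15), and DFR, dihydroflavonol reductase (log2 difference -2.59, SE 0.26, adjusted p = 1.32e-10).

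Of 13 NLR immune receptor genes, 0 were higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 0.000237). The 10 with at least 1 CPM in each accession did not pass as a set (adjusted p = 0.0879), nor did they at 10, 23 and 27 °C (0.41, 0.0879 and 0.182). RPP2A and RPP2B, a neighbouring pair of receptors against downy mildew, had no count in the 12 IP-Svi-0 libraries and 17.35 ± 6.90 and 13.9 ± 6.05 CPM in Col-0. Against a floor of 3 counts over the 12 libraries, RPP2A was at least 44.4-fold and RPP2B at least 35.7-fold lower. Of 26 photosynthesis genes, 8 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.0261; adjusted p = 0.649 with an estimated correlation; 0.0538 without Col-0 10 °C replicate 2, 0.0571 without IP-Svi-0 16 °C replicate 3 and 0.0544 without IP-Svi-0 23 °C replicate 3). With the covariate the list did not pass (adjusted p = 0.127). RBCS2B and RBCS1A, small subunits of Rubisco, were higher (0.86, SE 0.13 and 0.81, SE 0.15). MBF1C, a coactivator of the heat response, had 38.3 ± 22.8 against 488 ± 137 CPM (log2 difference -3.94, SE 0.17, adjusted p = 5.08e-21) and shares 312 bp of exon with AT3G04685. DREB2A, a factor of drought and heat response, was higher (log2 difference 1.80, SE 0.27, adjusted p = 1.63e-06) and shares 73 bp of exon with AT5G05420, and ROF2, a chaperone-binding protein, was lower (log2 difference -2.23, SE 0.39, adjusted p = 2.41e-05).

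The other lists did not pass as sets. Of 8 heat shock genes, 1 was higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.233), with a median of 0.14 and a mean of -0.50. Of 12 clock genes, 3 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.39), among them PRR3 (1.16, SE 0.18) and the light receptor ZTL (1.03, SE 0.20). Of 8 thermomorphogenesis genes, 1 was higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.584), and the expansin EXPA8 was higher (1.31, SE 0.18). Of 10 genes of the autonomous and vernalization pathways, 0 were higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.67). Among 5 gibberellin genes, 0 were higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.729). Of 5 genes of salicylic acid defence, 0 were higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.461), the lower one EDS5, an exporter of the hormone from chloroplasts that shares 213 bp of exon with AT4G39040 (-1.34, SE 0.14). Of 10 jasmonate response genes, 2 were higher and 1 lower, or 2 and 2 when adjusted over the list alone (camera adjusted p = 0.867), with a median of -0.06 although the test pointed upward. Of 8 seed storage genes, 4 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.121). Among 3 root markers, 1 was higher and 0 lower, or 2 and 0 when adjusted over the list alone (camera adjusted p = 0.461), with PRP3 higher (1.42, SE 0.23).

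By edgeR, 3298 genes differed in the mean over all temperatures, 1616 higher and 1682 lower in IP-Svi-0 (1349 and 1246 with the covariate). At all 4 temperatures and in the same direction 324 genes differed, 57 higher and 267 lower. Besides ESP and AOP2, the largest among genes with a mean of at least 1 CPM in both accessions included HEI10, a ligase of meiotic crossovers (697 ± 285 against 20.4 ± 17.1 CPM; log2 difference 5.15, SE 0.20, adjusted p = 1.77e-22), which shares 931 bp of exon with MRD1. MRD1 (5.64, SE 0.40), itself opposite AT1G07887 too, AT2G36540 (6.41, SE 0.33), AT4G32230 (6.45, SE 0.37) and the pseudogene AT2G12040 (8.64, SE 0.35) were higher too, and the pseudogene AT3G44035 had 1477 counts against 3. With 1 library left out, MRD1 ranged from 5.485 to 6.529 and AT2G36540 from 6.216 to 6.967. AT4G32230 then ranged from 6.294 to 7.487 and AT2G12040 from 8.478 to 9.67. By the same limit the largest toward Col-0 was the pseudogene AT2G11240, with 3.19 ± 4.66 against 7414 ± 2766 CPM (log2 difference -11.91, SE 0.36, adjusted p = 6.53e-25), which shares 1056 bp of exon with AT2G11225. AT5G49440 (-10.85, SE 0.31), AT3G06433 (-7.41, SE 0.25), ECS1 (-7.05, SE 0.32), AT5G66053 (-6.89, SE 0.21), the glycosyltransferase UGT76E12 (-6.61, SE 0.29), AT2G09800 (-6.60, SE 0.29) and AT1G23130 (-6.27, SE 0.20) followed. AT5G66053 lies opposite AT5G66052, AT2G09800 opposite AT2G09795 and UGT76E12 opposite AT3G46658. Of genes called at both 10 and 16 °C, 151 were higher at both and 526 lower at both, where 23.2 and 84.7 would be shared by chance, and 0 were opposite. Genes called in opposite directions were 19 for 10 and 23 °C, 9 for 10 and 27 °C, 1 for 16 and 23 °C, 1 for 16 and 27 °C, and 0 for 23 and 27 °C.

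Genes with counts in 1 accession and next to none in the other were counted without a test, as a mean under 0.05 CPM against at least 1 CPM. A single count in 1 library lifted the mean over 12 libraries above 0.05 CPM. Near absent therefore meant no count at all, and 1 stray read takes a gene out. There were 387 such genes, the same with a limit of 0.02 CPM, of which 284 were near absent in IP-Svi-0 and 103 in Col-0. Without the libraries of 1 replicate number there were 339 to 375 in IP-Svi-0 and 145 to 154 in Col-0. AT4G01595 (opposite AT4G01593) had no count in IP-Svi-0 and 540.1 ± 147 CPM in Col-0, at least 1383-fold more against a floor of 3 counts over the 12 libraries. AT1G24996 (at least 1066-fold), DRP4A, a dynamin-related gene opposite AT1G60525 (at least 822-fold), and the pseudogene AT1G34842, opposite AT1G34844 (at least 446-fold) followed. In Col-0, no count was found at the pseudogenes AT1G37057 (at least 155-fold), AT4G20365 (at least 109-fold) and AT3G44793 (at least 28.4-fold), or at AT5G12960 (at least 30.2-fold). Reads of IP-Svi-0 were aligned to the Col-0 genome, so reads from diverged sequence may be missing at any gene lower in IP-Svi-0.

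At 10 °C the question was which genes differ between the accessions in the cold. KIN1 and KIN2 had fewer counts in IP-Svi-0, the first with 44.1 ± 17.8 against 498 ± 42.6 CPM (SD, n = 3 each; log2 difference -3.46, SE 0.36, adjusted p = 1.93e-09), and the second with a log2 difference of -3.13, SE 0.28, adjusted p = 2.92e-11. Of 19 cold response genes, 1 was higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 0.00123). The higher one was BAM3, a beta-amylase (log2 difference 1.103, SE 0.24, adjusted p = 0.00101), which shares 531 bp of exon with AT4G06665. Of 26 photosynthesis genes, 16 were higher and 0 lower, or 19 and 0 when adjusted over the list alone (camera adjusted p = 7.96e-09; adjusted p = 0.248 with an estimated correlation), and the list passed with the covariate (adjusted p = 6.45e-08). RBCS2B had 3817 ± 474 against 1047 ± 87.8 CPM (log2 difference 1.87, SE 0.27, adjusted p = 2.37e-06), and RBCS1A had a log2 difference of 1.84, SE 0.30, adjusted p = 1.35e-05. Of 13 NLR genes, 1 was higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.0368; adjusted p = 0.248 with an estimated correlation; 0.0909 without Col-0 10 °C replicate 1, 0.0668 without Col-0 10 °C replicate 2, 0.0937 without Col-0 10 °C replicate 3, 0.0831 without IP-Svi-0 10 °C replicate 1 and 0.102 without IP-Svi-0 10 °C replicate 3), with RPP7 at 1 count in IP-Svi-0 and 51 in Col-0. Of 13 flavonoid genes, 0 were higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.0678), among them UGT79B1 (-4.34, SE 0.50) and DFR (-2.00, SE 0.41).

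Among flowering genes at 10 °C, SOC1 had 70 counts in IP-Svi-0 and 3 in Col-0 (31.9 ± 7.68 against 2.11 ± 2.36 CPM, adjusted p = 1.94e-05). FLM was lower (log2 difference -1.83, SE 0.47, adjusted p = 0.00403), and FLC did not pass (log2 difference 1.67, SE 0.72, adjusted p = 0.0865, or adjusted p = 0.041 with the covariate). CDF3 (log2 difference -2.41, SE 0.33, adjusted p = 6.08e-07) and VRN2 (log2 difference -2.46, SE 0.62, adjusted p = 0.00356) were lower, and TEM1, a repressor of FT, was higher (log2 difference 1.195, SE 0.30, adjusted p = 0.00298). Of 16 flowering repressors, 1 was higher and 4 lower, the same when adjusted over the list alone (camera adjusted p = 0.671). ZTL (1.81, SE 0.43), EXPA8 (1.37, SE 0.35), AOS, of jasmonate synthesis (1.29, SE 0.29), ESP (6.79, SE 0.66) and AOP2 (5.13, SE 0.44) were higher. MBF1C (-5.51, SE 0.38), EDS5 (-1.61, SE 0.28) and MAM1, of glucosinolate chain elongation (-1.13, SE 0.25), were lower. AGL67, a MADS-box gene that shares 247 bp of exon with AT1G77960, was called at this temperature alone, with 1.90 ± 1.82 against 41.2 ± 13.1 CPM (log2 difference -4.06, SE 0.64, adjusted p = 8.8e-06). By edgeR, 2422 genes differed, 968 higher and 1454 lower, and 1054 with the covariate, of which 876 were shared. Genes without an overlap made up 75.6% of the higher genes and 38.4% of the lower, against 62.8% of those tested.

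At 16 °C the same question was asked of 12-day seedlings. KIN2 had 10.7 ± 7.86 against 102 ± 6.77 CPM (SD, n = 3; log2 difference -3.31, SE 0.38, adjusted p = 1.88e-08) and COR15A 6.35 ± 4.70 against 61.1 ± 25.4 CPM (log2 difference -3.37, SE 0.53, adjusted p = 1.15e-05). Of 19 cold response genes, 0 were higher and 7 lower, or 1 and 7 when adjusted over the list alone (camera adjusted p = 0.000368). Of 13 flavonoid genes, 0 were higher and 6 lower, the same when adjusted over the list alone (camera adjusted p = 5.53e-05; adjusted p = 0.0508 with an estimated correlation), with DFR lower (log2 difference -2.43, SE 0.43, adjusted p = 0.000108) and UGT79B1 at 2 counts against 69. Of 13 NLR genes, 0 were higher and 4 lower, or 0 and 7 when adjusted over the list alone (camera adjusted p = 8.97e-05). Of 26 photosynthesis genes, 2 were higher and 0 lower, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.00316; adjusted p = 0.575 with an estimated correlation; 0.0698 without IP-Svi-0 16 °C replicate 3), and the list did not pass with the covariate (adjusted p = 0.0971). FRL2 (log2 difference -2.89, SE 0.56, adjusted p = 0.000306), CDF3 (log2 difference -2.88, SE 0.34, adjusted p = 4.17e-08), MBF1C (-4.45, SE 0.36), EDS5 (-1.73, SE 0.29) and ESM1 (-1.28, SE 0.26) were lower. PR2, a glucanase of the salicylic acid response, had 43 counts against 0 in Col-0 (adjusted p = 0.00218; at least 6.35-fold higher against a floor of 3 counts over the 3 libraries).

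ESP (4.21, SE 0.57) and AOP2 (3.99, SE 0.38) were higher at 16 °C. The difference of ESP was 6.76 without Col-0 16 °C replicate 3, which held 138 of the 161 counts of Col-0. SOC1 was higher (log2 difference 1.90, SE 0.55, adjusted p = 0.0243), but its adjusted p was 0.115 without Col-0 16 °C replicate 1, 0.0514 without Col-0 16 °C replicate 2, 0.0584 without Col-0 16 °C replicate 3, 0.123 without IP-Svi-0 16 °C replicate 1 and 0.0615 without IP-Svi-0 16 °C replicate 3, and 0.0842 by DESeq2. FLM was lower (log2 difference -1.96, SE 0.54, adjusted p = 0.0156), with an adjusted p of 0.267 without Col-0 16 °C replicate 1, and FLC did not pass (log2 difference 1.22, SE 0.62, adjusted p = 0.246). At FLC, Col-0 16 °C replicates 1, 2 and 3 had 2.98, 6.30 and 20.5 CPM. With 1 library left out, its difference ranged from 0.758 to 2.175. By edgeR, 830 genes differed, 242 higher and 588 lower. The count was 520 without Col-0 16 °C replicate 3, 528 without IP-Svi-0 16 °C replicate 1, and 565 with the covariate. Organelle genes held 3.24 to 9.72% of the gene counts in Col-0 at 16 °C, and 11 of the lower genes were organelle genes.

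At 23 °C, the temperature used as the control, KIN2 (log2 difference -2.94, SE 0.39, adjusted p = 4.65e-07) and COR15A (log2 difference -3.16, SE 0.68, adjusted p = 0.00115) were lower in IP-Svi-0 (n = 3 each). Of 19 cold response genes, 0 were higher and 6 lower, or 1 and 7 when adjusted over the list alone (camera adjusted p = 0.000826). DFR had 4.34 ± 2.22 against 70.6 ± 15.4 CPM (log2 difference -3.98, SE 0.61, adjusted p = 7.55e-06), and of 13 flavonoid genes, 0 were higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 2.93e-05). Of 13 NLR genes, 0 were higher and 5 lower, or 0 and 6 when adjusted over the list alone (camera adjusted p = 0.000237), with RPP2A at least 11.5-fold and RPP2B at least 9.07-fold lower against the floor of 3 counts over 3 libraries. FLC had 16.8 ± 3.91 against 2.83 ± 3.00 CPM (log2 difference 2.65, SE 0.70, adjusted p = 0.0108), with an adjusted p of 0.052 without Col-0 23 °C replicate 1, 0.0967 without Col-0 23 °C replicate 2 and 0.0534 without IP-Svi-0 23 °C replicate 3. SOC1 (log2 difference 1.26, SE 0.53, adjusted p = 0.154) and FLM (log2 difference -1.49, SE 0.69, adjusted p = 0.211) did not pass. FRL2 (log2 difference -2.20, SE 0.47, adjusted p = 0.00116), CDF3 (log2 difference -1.52, SE 0.30, adjusted p = 0.000407), MBF1C (-2.98, SE 0.33), ESM1 (-1.53, SE 0.28) and VSP2, a jasmonate-induced storage protein (-3.38, SE 0.59), were lower. PRR3 (1.65, SE 0.33), EXPA8 (1.46, SE 0.36), ESP (6.74, SE 0.65) and AOP2 (5.34, SE 0.36) were higher. DREB2A had 29.6 ± 4.41 against 4.14 ± 1.68 CPM (log2 difference 2.85, SE 0.51, adjusted p = 9.85e-05), and PUP7, a purine permease, had 25.3 ± 3.27 against 2.01 ± 2.02 CPM (log2 difference 3.55, SE 0.64, adjusted p = 9.85e-05) and shares 225 bp of exon with AT4G18203. By edgeR, 801 genes differed, 308 higher and 493 lower, and 1040 with the covariate.

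At 27 °C the question was which genes differ in the warmth, and seed genes were among them. CRU3, a cruciferin storage protein, had 629.5 ± 204 against 23.0 ± 19.7 CPM (SD, n = 3; log2 difference 4.67, SE 0.67, adjusted p = 2.04e-06), and EM1, a late embryogenesis protein, had 67 counts in IP-Svi-0 against 2. Of 8 seed storage genes, 6 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 7.96e-09; adjusted p = 0.0552 with an estimated correlation). RD29B, induced by abscisic acid, was higher (log2 difference 2.18, SE 0.53, adjusted p = 0.00437), and KIN2 was lower (log2 difference -1.82, SE 0.34, adjusted p = 0.000168). Of 19 cold response genes, 1 was higher and 5 lower, the same when adjusted over the list alone (camera adjusted p = 0.00967). Among 25 glucosinolate genes, 6 were higher and 2 lower, or 7 and 2 when adjusted over the list alone (camera adjusted p = 0.000704; adjusted p = 0.0818 with an estimated correlation), with TGG2, a myrosinase, lower (-1.20, SE 0.29). Among 13 flavonoid genes, 0 were higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.0308; adjusted p = 0.349 with an estimated correlation). Of 13 NLR genes, 0 were higher and 5 lower, or 0 and 6 when adjusted over the list alone (camera adjusted p = 0.000704; adjusted p = 0.0552 with an estimated correlation), with SNC1 at 0 counts against 66, at least 21.4-fold lower against the floor of 3 counts over 3 libraries. WRKY70, a factor of salicylic acid signalling, had 4.37 ± 0.645 against 29.5 ± 6.64 CPM (log2 difference -2.74, SE 0.55, adjusted p = 0.000438).

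FRL2 (log2 difference -2.63, SE 0.43, adjusted p = 2.03e-05), CDF3 (log2 difference -1.74, SE 0.29, adjusted p = 3.59e-05), MBF1C (-2.83, SE 0.32), ROF2 (-1.48, SE 0.33), EDS5 (-1.25, SE 0.28) and ESM1 (-1.39, SE 0.28) were lower at 27 °C. ESP (6.56, SE 0.64), AOP2 (5.47, SE 0.36), EXPA8 (1.33, SE 0.34) and CORI3, a jasmonate-induced enzyme (1.299, SE 0.31), were higher. FLC (log2 difference 1.32, SE 0.64, adjusted p = 0.254) and FLM (log2 difference -0.25, SE 0.57, adjusted p = 0.885) did not pass, and SOC1, with 9 counts against 2, did not either (adjusted p = 0.206). By edgeR, 812 genes differed, 251 higher and 561 lower, and 1076 with the covariate.

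The temperature comparisons asked how each accession differed from its own seedlings at 23 °C, which serve as control for all 3 of its comparisons. In Col-0 at 10 °C, COR15A (AT2G42540, chromosome 2 from 17710441 to 17712330, protein-coding) rose, with 894 ± 244 against 27.0 ± 8.08 CPM (SD, n = 3; log2 difference 5.005, SE 0.38, adjusted p = 7.68e-12), and so did COR15B (log2 difference 4.67, SE 0.40, adjusted p = 7.71e-11), which shares 468 bp of exon with AT2G42520. Of 19 cold response genes, 8 were higher and 2 lower, or 9 and 2 when adjusted over the list alone (camera adjusted p = 3.9e-10). ZAT10 (log2 difference -2.67, SE 0.44, adjusted p = 8.48e-05) and CZF1 (log2 difference -1.52, SE 0.29, adjusted p = 0.000486), zinc-finger stress proteins, fell, as did the chaperone HSP70 (log2 difference -4.15, SE 0.49, adjusted p = 1.75e-07). LHCB1.1 (log2 difference 4.49, SE 0.56, adjusted p = 4.55e-07) and LHCB1.2 (log2 difference 4.17, SE 0.70, adjusted p = 9.42e-05), light-harvesting proteins, rose, while RBCS2B (log2 difference -1.60, SE 0.27, adjusted p = 0.000117) and RBCS3B (log2 difference -1.57, SE 0.30, adjusted p = 0.000514) fell. Of 26 photosynthesis genes, 11 were higher and 3 lower, or 14 and 4 when adjusted over the list alone (camera adjusted p = 2.97e-08; adjusted p = 0.277 with an estimated correlation). Among 8 heat shock genes, 0 were higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.0341; adjusted p = 0.277 with an estimated correlation; 0.263 without Col-0 10 °C replicate 1 and 0.0842 without Col-0 23 °C replicate 3). Of 10 jasmonate response genes, 1 was higher and 5 lower, the same when adjusted over the list alone (camera adjusted p = 2.52e-05), with VSP1 at 0 counts against 41, at least 8.70-fold lower, and VSP2 at 3 against 99. CYP707A3, which breaks down abscisic acid, had 0 counts against 31 (at least 6.27-fold lower, floor of 3 counts). GAI, a repressor of gibberellin response, rose (log2 difference 1.82, SE 0.35, adjusted p = 0.000733), and so did ESM1 (log2 difference 1.08, SE 0.25, adjusted p = 0.00456).

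FLM in Col-0 rose at 10 °C (log2 difference 1.52, SE 0.46, adjusted p = 0.0371), but its adjusted p was 0.0802 without Col-0 10 °C replicate 2, 0.168 without Col-0 10 °C replicate 3, 0.134 without Col-0 23 °C replicate 1 and 0.12 without Col-0 23 °C replicate 3. By edgeR, 675 genes changed, 387 higher and 288 lower, of which 17 higher were organelle genes. The count was 398 and 352 without Col-0 10 °C replicate 2 or 3, and 403 without Col-0 23 °C replicate 1. With the covariate it was 682, of which 420 were shared, and the balance reversed to 249 higher and 433 lower.

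In Col-0 at 16 °C, CZF1 (log2 difference -2.16, SE 0.32, adjusted p = 6.01e-05) and HSP70 (log2 difference -2.25, SE 0.41, adjusted p = 0.00163) fell. MYB77, an auxin-related factor, had 0 counts against 69 (adjusted p = 5.8e-05; at least 10.2-fold lower, floor of 3 counts), DIC2, a mitochondrial carrier, 2 against 116, and NUDT21, a nudix hydrolase, 2 against 108. Counts at the ribosomal RNA genes AT2G01010 (log2 difference 9.11, SE 1.57, adjusted p = 0.000749) and AT2G01021 (log2 difference 4.56, SE 0.76, adjusted p = 0.000448) rose, and the amount of ribosomal RNA left in a library can change such counts. Of 10 jasmonate response genes, 0 were higher and 2 lower, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.000117). Of 12 clock genes, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.0306; adjusted p = 0.161 with an estimated correlation; 0.109 without Col-0 16 °C replicate 2 and 0.141 without Col-0 16 °C replicate 3). Among 8 seed storage genes, 0 were higher and 0 lower, or 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.578 with an estimated correlation; 0.275 without Col-0 23 °C replicate 1 and 0.154 without Col-0 23 °C replicate 2). Neither of these 2 lists passed with the covariate (adjusted p = 0.142 and 0.434). Of 13 flavonoid genes, 1 was higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.161 with an estimated correlation). By edgeR, 124 genes changed, 52 higher and 72 lower, of which 17 higher were organelle genes. The count was 52 and 77 without Col-0 16 °C replicate 2 or 3, and 55 and 67 without Col-0 23 °C replicate 1 or 2.

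In Col-0 at 27 °C, the chaperone HSP90.1 rose, with 103 ± 18.8 against 17.3 ± 4.51 CPM (SD, n = 3; log2 difference 2.58, SE 0.29, adjusted p = 7.35e-07), as did HSP70 (log2 difference 1.60, SE 0.26, adjusted p = 0.00147) and ROF2 (log2 difference 2.09, SE 0.36, adjusted p = 0.00283). Of 8 heat shock genes, 3 were higher and 0 lower, or 4 and 0 when adjusted over the list alone (camera adjusted p = 5.98e-19). Among flavonoid genes, 0 were higher and 1 lower, or 0 and 6 when adjusted over the list alone (camera adjusted p = 1.04e-09). Of 12 clock genes, 0 were higher and 0 lower, or 2 and 0 when adjusted over the list alone (camera adjusted p = 0.00115). Among 10 jasmonate response genes, 0 were higher and 0 lower, or 0 and 1 when adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.306 with an estimated correlation; 0.476 without Col-0 23 °C replicate 1, 0.111 without Col-0 23 °C replicate 3, 0.0733 without Col-0 27 °C replicate 2 and 0.452 without Col-0 27 °C replicate 3), which did not pass with the replicate block (adjusted p = 0.0518). Of 8 seed storage genes, 0 were higher and 3 lower, or 0 and 5 when adjusted over the list alone (camera adjusted p = 5.99e-09; adjusted p = 0.0679 with an estimated correlation). The control libraries differed at CRU3, with 410, 281 and 23.9 CPM in Col-0 23 °C replicates 1, 2 and 3. The adjusted p of CRU3 was 0.277 without Col-0 23 °C replicate 1, 0.0664 without Col-0 23 °C replicate 2, 0.127 without Col-0 27 °C replicate 1 and 0.197 without Col-0 27 °C replicate 3. That of OLEO1 (opposite AT4G25150) was 0.439 without Col-0 23 °C replicate 1, 0.0508 without Col-0 23 °C replicate 2, 0.223 without Col-0 27 °C replicate 2 and 0.125 without Col-0 27 °C replicate 3, and that of AT2S3 0.545 without Col-0 23 °C replicate 1, 0.0792 without Col-0 27 °C replicate 1, 0.0924 without Col-0 27 °C replicate 2 and 0.055 without Col-0 27 °C replicate 3. The list passed without any 1 of these libraries. Among 26 photosynthesis genes, 0 were higher and 0 lower, or 0 and 2 when adjusted over the list alone (camera adjusted p = 0.0197; adjusted p = 0.734 with an estimated correlation; 0.0637 without Col-0 23 °C replicate 2, 0.212 without Col-0 27 °C replicate 1 and 0.0693 without Col-0 27 °C replicate 3). By edgeR, 11 genes changed, 5 higher and 6 lower, and 34 with the covariate, 20 higher and 14 lower. The count was 5 and 7 without Col-0 23 °C replicate 1 or 2, and 7 and 5 without Col-0 27 °C replicate 1 or 3.

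**Figure D4:**
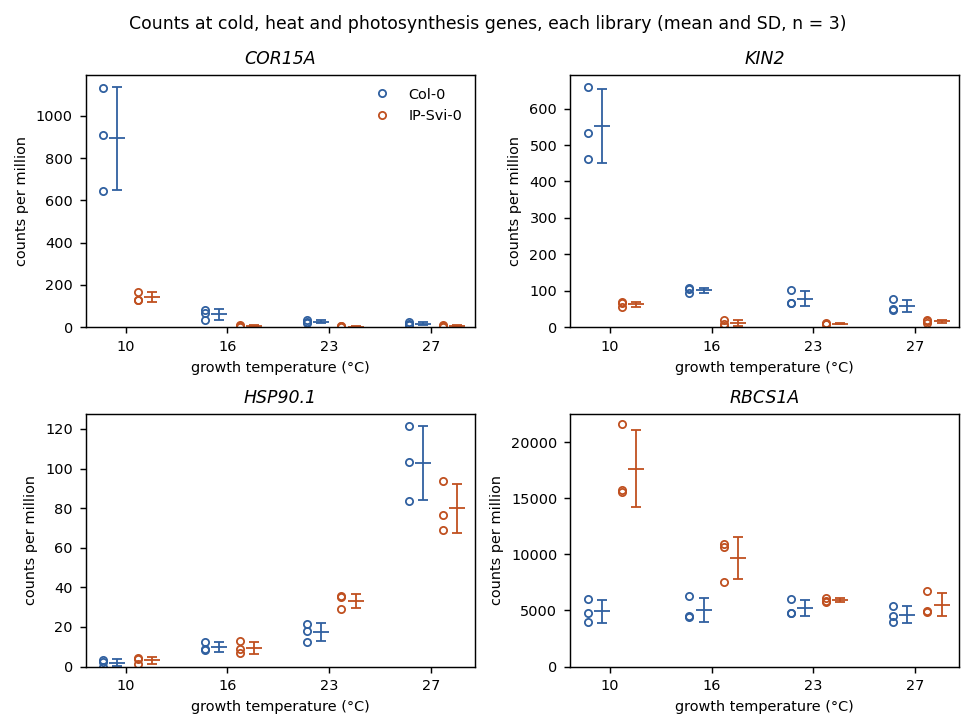
CPM (vertical axis) at COR15A, KIN2, HSP90.1 and RBCS1A in both accessions at 10, 16, 23 and 27 °C (horizontal axis); open circles are libraries, dashes and bars the mean and SD of 3 libraries, the lower bar cut at 0. COR15A in Col-0 had 894 CPM at 10 °C and 27.0 CPM at 23 °C.

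In IP-Svi-0 at 10 °C, LHCB1.1 rose, with 2462 ± 694 against 31.8 ± 2.59 CPM (SD, n = 3; log2 difference 6.26, SE 0.64, adjusted p = 5.08e-09), as did LHB1B1 (log2 difference 6.11, SE 0.61, adjusted p = 4.53e-09) and LHCB1.2 (log2 difference 5.68, SE 0.76, adjusted p = 1.2e-06). Of 26 photosynthesis genes, 20 were higher and 0 lower, or 21 and 0 when adjusted over the list alone (camera adjusted p = 1.33e-38). COR15A (log2 difference 5.505, SE 0.56, adjusted p = 5.08e-09) and COR15B (log2 difference 5.16, SE 0.56, adjusted p = 2.04e-08) rose, and of 19 cold response genes, 7 were higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 1.77e-05). HSP70 (log2 difference -3.96, SE 0.39, adjusted p = 3.13e-09) and HSP90.1 (log2 difference -3.36, SE 0.45, adjusted p = 1.2e-06) fell, and of 8 heat shock genes, 0 were higher and 4 lower, or 0 and 7 when adjusted over the list alone (camera adjusted p = 7.66e-07). PCC1, a gene of defence and the clock, had 40 counts against 0 (at least 8.55-fold higher, floor of 3 counts), and the cytochrome P450 CYP72A9 fell (log2 difference -4.82, SE 0.58, adjusted p = 2.01e-07). In the flavonoid list, 5 were higher and 0 lower, or 6 and 0 when adjusted over the list alone (camera adjusted p = 0.00146; adjusted p = 0.161 with an estimated correlation), with LDOX, an anthocyanin enzyme, higher (log2 difference 1.93, SE 0.49, adjusted p = 0.00554). Of 8 seed storage genes, 0 were higher and 5 lower, the same when adjusted over the list alone (camera adjusted p = 0.000288; adjusted p = 0.277 with an estimated correlation), with CRA1, a cruciferin, lower (log2 difference -3.10, SE 0.60, adjusted p = 0.000379). CDF5, which shares 1154 bp of exon with AT1G69572 (log2 difference -1.33, SE 0.31, adjusted p = 0.00237), ELF4, a clock gene (log2 difference -1.55, SE 0.35, adjusted p = 0.00201), and VSP1 (log2 difference -2.70, SE 0.59, adjusted p = 0.00146) fell, and ESM1 rose (log2 difference 2.04, SE 0.28, adjusted p = 2.15e-06). By edgeR, 1591 genes changed, 583 higher and 1008 lower, and 1145 with the covariate. The count was 1003 and 843 without IP-Svi-0 10 °C replicate 1 or 2, and 1035 without IP-Svi-0 23 °C replicate 3.

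In IP-Svi-0 at 16 °C, PCC1 had 47 counts against 0 (at least 11.5-fold higher, floor of 3 counts), and UBQ11, a polyubiquitin, rose (log2 difference 3.34, SE 0.63, adjusted p = 0.0034). CYP72A9 (log2 difference -3.10, SE 0.49, adjusted p = 0.000365), the receptor-like kinase CRK4 (log2 difference -3.12, SE 0.52, adjusted p = 0.000733) and HSP70 (log2 difference -1.81, SE 0.31, adjusted p = 0.00118) fell. Of 8 heat shock genes, 0 were higher and 2 lower, or 0 and 6 when adjusted over the list alone (camera adjusted p = 1.45e-07). Of 16 flowering repressors, 0 were higher and 0 lower, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.181 with an estimated correlation; 0.0671 without IP-Svi-0 16 °C replicate 1, 0.1 without IP-Svi-0 16 °C replicate 2, 0.141 without IP-Svi-0 23 °C replicate 1 and 0.108 without IP-Svi-0 23 °C replicate 3), which did not pass with the covariate (adjusted p = 0.0611) or with the replicate block (0.0518). Of 12 clock genes, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.161 with an estimated correlation; 0.125 without IP-Svi-0 16 °C replicate 2). Of 13 flavonoid genes, 0 were higher and 0 lower, or 4 and 0 when adjusted over the list alone (camera adjusted p = 0.00179; adjusted p = 0.161 with an estimated correlation; 0.0554 without IP-Svi-0 16 °C replicate 2 and 0.0525 without IP-Svi-0 23 °C replicate 1). Among 26 photosynthesis genes, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 8.72e-06; adjusted p = 0.399 with an estimated correlation). By edgeR, 80 genes changed, 17 higher and 63 lower, and 49 with the covariate. The count was 129 and 38 without IP-Svi-0 16 °C replicate 1 or 3, and 49, 44 and 24 without IP-Svi-0 23 °C replicate 1, 2 or 3.

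In IP-Svi-0 at 27 °C, edgeR called 0 genes, with 681 under an unadjusted p of 0.05, 12 by DESeq2 and 14 with the covariate. Some lists passed as sets. Of 8 heat shock genes, 0 were higher and 0 lower, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.000238). Of 5 genes of salicylic acid defence, 0 were higher and 0 lower, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.000777). Of 8 seed storage genes, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.000402; adjusted p = 0.291 with an estimated correlation; 0.0508 without IP-Svi-0 27 °C replicate 1). Camera compares the genes of a list with all other genes, so a list can pass with few genes called. All calls of lists in this report held with an estimated correlation unless a p with it is given, and without any 1 library of the groups compared unless that library is named.

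The interaction asked whether the accessions respond differently to temperature, as the change in IP-Svi-0 minus that in Col-0. At 10 °C, SZF1, a zinc-finger stress protein, had 16.4 ± 7.20 CPM in Col-0 against 140.4 ± 8.93 CPM at 23 °C, and 56.0 ± 24.2 against 17.3 ± 2.92 CPM in IP-Svi-0 (SD, n = 3; log2 difference 4.601, SE 0.53, adjusted p = 1.65e-06). SRC2, a membrane protein with a C2 domain (log2 difference 2.35, SE 0.36, adjusted p = 0.00052), WRKY33, a defence factor (log2 difference 2.56, SE 0.47, adjusted p = 0.00394), AT4G34150 (log2 difference 2.99, SE 0.48, adjusted p = 0.000548) and CZF1 (log2 difference 2.08, SE 0.42, adjusted p = 0.00696) also differed upward. WRKY33 shares 49 bp of exon with AT2G38480. MBF1C (log2 difference -2.54, SE 0.50, adjusted p = 0.00592), AT5G33330, which shares 66 bp of exon with CUE1 (log2 difference -2.83, SE 0.45, adjusted p = 0.00052), and AT5G14550, which shares 208 bp of exon with MIR398b (log2 difference -2.72, SE 0.48, adjusted p = 0.00224), differed downward. LHCB6, a light-harvesting protein that shares 246 bp of exon with AT1G05207, differed upward (log2 difference 1.68, SE 0.36, adjusted p = 0.00901). Of 26 photosynthesis genes, 8 were higher and 0 lower, or 20 and 0 when adjusted over the list alone (camera adjusted p = 5.69e-14; adjusted p = 0.216 with an estimated correlation).

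By edgeR, 550 genes differed in their response to 10 °C, 144 higher and 406 lower. With the covariate 34 differed, of which 25 were shared, and the balance reversed to 27 higher and 7 lower. The count was 897, 119 and 135 without Col-0 10 °C replicate 1, 2 or 3, and 99 and 129 without Col-0 23 °C replicate 1 or 2. It was 159, 88 and 851 without IP-Svi-0 10 °C replicate 1, 2 or 3, and 255, 166 and 155 without IP-Svi-0 23 °C replicate 1, 2 or 3. SZF1, SRC2 and WRKY33 were called in every one of these fits. Over all 3 interaction terms, 144 genes were called, and 43 with the covariate, 29 of them shared. That count was 342, 62 and 59 without Col-0 10 °C replicate 1, 2 or 3, 323 without Col-0 16 °C replicate 1, 48 and 57 without Col-0 23 °C replicate 1 or 2, and 68 and 60 without Col-0 27 °C replicate 1 or 2. It was 61, 36 and 233 without IP-Svi-0 10 °C replicate 1, 2 or 3, 77, 49 and 56 without IP-Svi-0 23 °C replicate 1, 2 or 3, and 69, 68 and 383 without IP-Svi-0 27 °C replicate 1, 2 or 3.

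At 16 °C the interaction had 0 genes by edgeR, with 1287 under an unadjusted p of 0.05 and 1 by DESeq2, and at 27 °C it had 0, with 377 and 0. The count at 16 °C was 13, 1 and 2 without Col-0 16 °C replicate 1, 2 or 3, 1 without Col-0 23 °C replicate 3, and 2 and 2 without IP-Svi-0 16 °C replicate 2 or 3. The count at 27 °C was 3 without Col-0 23 °C replicate 3. As sets at 16 °C, of 8 heat shock genes, 0 were higher and 0 lower, or 0 and 1 when adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.248 with an estimated correlation; 0.0877 without Col-0 16 °C replicate 3, 0.0574 without Col-0 23 °C replicate 1 and 0.0657 without IP-Svi-0 16 °C replicate 1). Among 26 photosynthesis genes, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 8.84e-06; adjusted p = 0.423 with an estimated correlation). At 27 °C, of 8 heat shock genes, 0 were higher and 0 lower, or 0 and 2 when adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.248 with an estimated correlation; 0.14 without Col-0 23 °C replicate 1, 0.0819 without IP-Svi-0 23 °C replicate 1 and 0.0702 without IP-Svi-0 27 °C replicate 3). Among 5 genes of salicylic acid defence, 0 were higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 0.0076; adjusted p = 0.216 with an estimated correlation; 0.0909 without IP-Svi-0 27 °C replicate 3). The heat shock list passed at neither temperature with the covariate (adjusted p = 0.192 at 16 °C and 0.165 at 27 °C). Of 10 jasmonate response genes, 0 were higher and 0 lower, or 1 and 0 when adjusted over the list alone (camera adjusted p = 0.00633; adjusted p = 0.216 with an estimated correlation; 0.0633 without Col-0 27 °C replicate 3 and 0.0518 without IP-Svi-0 27 °C replicate 3). Among 8 seed storage genes, 0 were higher and 0 lower, or 5 and 0 when adjusted over the list alone (camera adjusted p = 1.86e-12; adjusted p = 0.133 with an estimated correlation). Responses of the accessions to 10 °C overlapped, with 75 genes higher and 102 lower in both where 22.3 and 28.8 would be shared by chance, and 11 opposite.

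**Figure D5:**
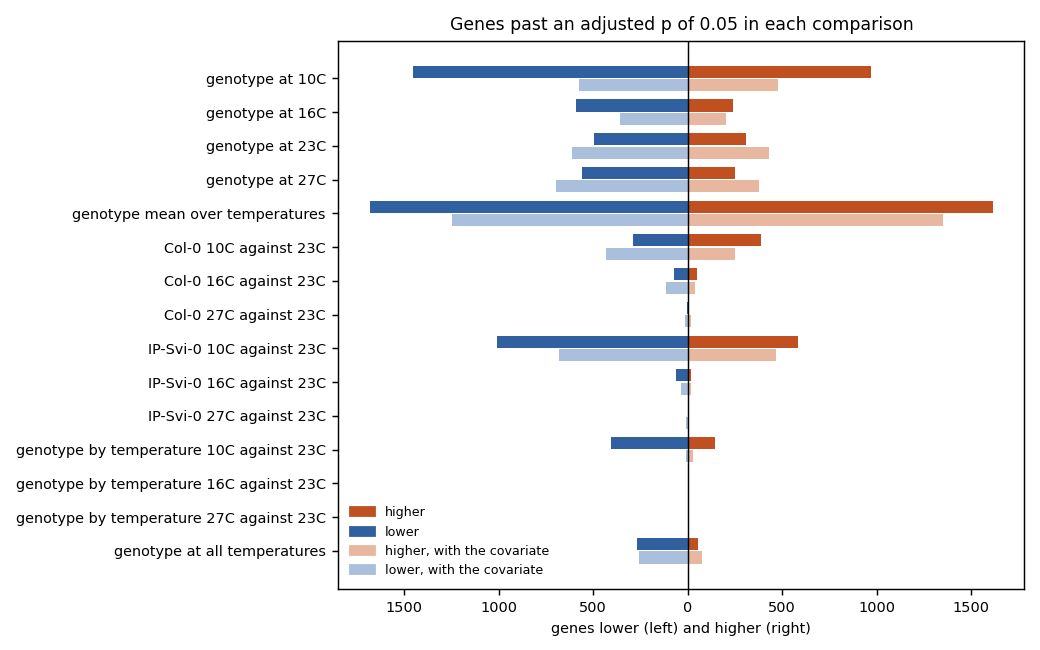
Number of genes called (horizontal axis) in each of 15 comparisons, lower to the left and higher to the right of 0, without (dark) and with (pale) the covariate. At 10 °C the accessions differed at 2422 genes without it and 1054 with it.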

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

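In the first pattern below, all tests but the correlation across pairs were chosen after their values were seen, the permutation of residuals after the data were seen, and in the other 2 the tests were set before, although the covariate and the thinned libraries used there were chosen after the data were seen.

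The response to 10 °C differed between the accessions, by the interaction test, at 550 genes, and over all 3 interaction terms at 144. The log2 difference between responses was 4.601 for SZF1, 2.99 for AT4G34150, 2.56 for WRKY33, 2.35 for SRC2, -2.83 for AT5G33330 and -2.72 for AT5G14550. These 6 kept their call without any 1 library and with the covariate, where the adjusted p was 4.34e-05, 0.00958, 0.00253, 5.13e-05, 0.0268 and 0.0268. They had been named for a small p over all 3 interaction terms, which favours keeping the call. The log2 difference was 2.23 for AT5G19240, whose adjusted p was 0.0557 without IP-Svi-0 10 °C replicate 2. AT1G68250 had -4.85 (adjusted p = 0.209 with the covariate). For AT2G41640 the model gave 7.59, but with 2 counts in Col-0 at 10 °C and 0 in IP-Svi-0 at 23 °C its size is not a measured fold (adjusted p = 0.0897 with the covariate).

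HR4, a resistance gene relative, had a modelled difference of 5.28, whose size is not a measured fold either since IP-Svi-0 at 23 °C had 0 counts, with an adjusted p of 0.0715 without Col-0 10 °C replicate 2, 0.0589 without Col-0 23 °C replicate 1, 0.0589 without Col-0 23 °C replicate 2, 0.0551 without IP-Svi-0 10 °C replicate 1, 0.106 without IP-Svi-0 10 °C replicate 2, 0.0821 without IP-Svi-0 23 °C replicate 1, 0.0909 without IP-Svi-0 23 °C replicate 2 and 0.0974 without IP-Svi-0 23 °C replicate 3. AGL67 had -4.99, with an adjusted p of 0.08 without IP-Svi-0 23 °C replicate 3. The ribosomal RNA gene AT2G01010 had -10.73, with an adjusted p of 0.528 without Col-0 10 °C replicate 2 and 0.0859 without IP-Svi-0 23 °C replicate 2. The chloroplast gene ATCG01010 had -5.20, with an adjusted p of 0.0977 without Col-0 10 °C replicate 2, 0.0802 without Col-0 23 °C replicate 1, 0.0617 without IP-Svi-0 10 °C replicate 1, 0.0794 without IP-Svi-0 10 °C replicate 2 and 0.135 without IP-Svi-0 23 °C replicate 2. With the covariate the adjusted p of HR4 was 0.076, of AGL67 0.277, of AT2G01010 0.0931 and of ATCG01010 0.398.

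Reads outside the gene counts also differed. Reads that did not align averaged 1.65% in IP-Svi-0 and 0.453 ± 0.0566% in Col-0, and reads of low alignment quality 5.83% and 2.85 ± 0.324% (SD, n = 12 each). Groups of 3 libraries were not tested for single deviating values.

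The first pattern weighed is that counts at genes lie opposite annotated genes: those under an opposite exon had 3.39 times the counts per kb. Genomic DNA as the only source of the counts, with a ratio near 1, does not allow this. Whether DNA gave part of the counts was not tested. The correlation across 852 pairs was 0.348, above its preset limit, but exchanging the strands leaves it as it is, so that limit was wrong. In 195 pairs the non-coding gene had more counts per kb than the coding one in 56.9% (exact 95% interval 49.7 to 64.0), where an interval above 50% would speak for the opposite strand and one below for the genes' own transcripts. The median was 48.4 counts per kb at these non-coding genes and 20.3 at their coding partners, for which no interval was computed. At most 3.61% of the reads of a library were counted at genes and 59.6 to 89.8% were assigned to no gene. This speaks against counting on the genes' own strand, but the low share had prompted the pattern, so it is no separate test. The few counts could still be a small leak of own transcripts. Neither source was therefore excluded at overlapping genes, and no biological explanation was tested.

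The second pattern is that the accessions differed most at 10 °C. Depth was excluded as the cause, since libraries thinned to the smallest total gave 1761 genes at 10 °C against 642, 555 and 513 at 16, 23 and 27 °C. With the share of counts at genes without an overlap as a covariate, 1054 genes were called instead of 2422, against 1040 at 23 °C and 1076 at 27 °C. A difference in strand leakage between libraries could therefore explain the excess. The share differed between the accessions at 10 °C, so the covariate may also have removed a biological response to cold, and this stayed open.

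The third pattern is that more genes were near absent in IP-Svi-0 than in Col-0, 2.76 times as many. The ratio depended on the setting. The numbers were 104 and 15 with at least 5 CPM in the other accession, and 339 to 375 and 145 to 154 without the libraries of 1 replicate number. Reads of IP-Svi-0 lost against the Col-0 reference could give this excess. Only genes of the Col-0 reference were counted, so a gene present in IP-Svi-0 alone could not appear. The design thus favoured an excess in this direction, and the ratio cannot decide between explanations. Deleted or diverged stretches would put such genes side by side, and 31.9% of 279 had a near-absent neighbour, where the highest of 1000 random draws from the 19717 nuclear genes with at least 1 CPM in Col-0 had 7.17% and the median 2.87%. Both explanations stayed open, since a deleted gene and a diverged gene both lose reads.

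Other assignments of the libraries to groups were tested. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, and in each comparison 1 split of 10, the real one, gave the most genes. At 10, 16, 23 and 27 °C the real split of the accessions gave 2264, 440, 997 and 837 genes and the highest other 0. In Col-0 the real split gave 736 at 10 °C, 178 at 16 °C and 38 at 27 °C, where the highest other gave 0, 0 and 16. In IP-Svi-0 it gave 1817, 35 and 26, where the highest other gave 0. In 100 assignments of accession within temperature, only the real one reached 324 genes at all 4 temperatures (highest other 0) and 3298 over all temperatures (0). Permuted accessions cannot test the interaction, since they mix the accessions within groups. Residuals of a model without interaction were therefore permuted among the libraries, with limma on log2 CPM with a prior count of 2. Of 100 sets only the real one gave 527 genes at 10 °C (highest other 1) and 123 over all 3 terms (highest other 83). At 16 °C 5 of 100 gave at least the real 3, and the highest gave 1468 genes, the cause of which was not examined. At 27 °C the real count was 0, which all 100 reach, so nothing was tested there.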

How the results depend on the processing

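Few reads were counted at genes, 1.41 to 3.61% of a library. Most 2-fold changes were missed in the 3 comparisons that were simulated, where depth was not varied. Every alternative below changed 1 choice, and the cause of each change was not tested unless the alternative tested fewer or other genes. The covariate, the thinned libraries, the fit without organelle genes and the separate fits were chosen after the data were seen. With the covariate the count was 1054 for the accessions at 10 °C, 34 for Col-0 at 27 °C, 49 and 14 for IP-Svi-0 at 16 and 27 °C, 34 and 1 for the interaction at 10 and 16 °C, and 43 over all interaction terms. With 2 groups alone it was 440 for the accessions at 16 °C, 38 for Col-0 at 27 °C, and 35 and 26 for IP-Svi-0 at 16 and 27 °C. Thinned libraries gave 513 for the accessions at 27 °C, and a fold of at least 2 gave 964 over all temperatures. Without a filter, which tested more genes, the count was 225 and 37 for Col-0 at 16 and 27 °C, 134 and 18 for IP-Svi-0, 65 and 13 for the interaction at 16 and 27 °C, and 391 over all interaction terms. DESeq2 gave 7 for Col-0 at 27 °C, 12 for IP-Svi-0 at 27 °C, 1 for the interaction at 16 °C and 349 over all interaction terms. Without organelle genes the count was 17 for Col-0 and 5 for IP-Svi-0 at 27 °C, and 4 for the interaction at 16 °C. Separate fits by overlap, which scaled each class alone, gave 19 for Col-0 at 27 °C, 145 and 12 for IP-Svi-0 at 16 and 27 °C, and 2 for the interaction at 16 °C. DESeq2 size factors gave 1 for IP-Svi-0 at 27 °C, and the replicate block gave 3 there and 3 for the interaction at 16 °C. With at least 5 CPM in the other accession, 119 genes were near absent, 104 in IP-Svi-0 and 15 in Col-0.

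Leaving out 1 library gave 520 to 998 genes for the accessions at 16 °C, 352 to 829, 52 to 124 and 5 to 13 for Col-0 at 10, 16 and 27 °C, and 843 to 1734 and 24 to 129 for IP-Svi-0 at 10 and 16 °C. It gave 88 to 897, 0 to 13 and 0 to 3 for the interaction at 10, 16 and 27 °C, and 36 to 383 over all terms. The change of ESP in Col-0 at 16 °C (2.55, adjusted p = 0.0182) had an adjusted p of 1 and a log2 change of -0.00874 without Col-0 16 °C replicate 3, and ranged to 3.10. AT1G29220 (opposite AT1G29200) at 10 °C (-3.87) became 0.94 without Col-0 10 °C replicate 1 and ranged down to -4.43. For the 333 named results, DESeq2 size factors kept 329 and weakened 4, DESeq2 kept 284 and weakened 49, the block kept 328 and weakened 5, and the covariate kept 283, weakened 47 and brought 3 past the threshold. Of the single-library fits of named genes, 2825 were the same, 387 weaker, 2 stronger and 2 reversed. The 60 set results include 6 that passed with the covariate but not in the main fit, and a result that passed in neither fit counted as kept. Of the 60, an estimated correlation kept 27 and weakened 33, and fry kept 46, weakened 12 and brought 2 past the threshold. The covariate kept 47, weakened 7 and brought 6 past it, and the block weakened 2. The minimum of 1 CPM weakened 4, all for the NLR list. Without 1 library, a test of lists chosen after the data were seen, 454 set results were the same, 39 weaker and 11 stronger. Libraries with the same replicate number were not more alike (mean r 0.0085 over 84 pairs, against -0.0041 over 168 pairs of different numbers). A fit without the 4 organelle-rich Col-0 libraries was not run, since it would remove all of Col-0 at 16 °C.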

Other observations

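All tests in this part were chosen after the values were seen. The genes near absent in IP-Svi-0 were not spread evenly over gene families. Of 143 NLR disease resistance genes, which recognise pathogens and vary between accessions, 21 were near absent (14.7%), against 1.42% of the 19717 nuclear genes with at least 1 CPM in Col-0 (odds ratio 12.9, 95% interval 7.57 to 21.0, Fisher's exact test adjusted p = 6.72e-15). The genes of each family were counted among these 19717. Of 284 pseudogenes, 61 were near absent (21.5%, odds ratio 24.1, adjusted p = 1.85e-53), and of 268 long non-coding RNA genes, 20 were (7.46%, odds ratio 5.97, adjusted p = 7.42e-09). F-box genes, whose products mark proteins for breakdown, had 7 of 154 (4.55%, adjusted p = 0.0231). Cytochrome P450 genes had 4 of 166 (adjusted p = 0.494), receptor-like kinases 4 of 193 (0.532) and ribosomal proteins 0 of 309 (0.0676). Defensin-like genes had 2 of 18 (0.0676) and UDP-glycosyltransferases 0 of 153 (0.494). In Col-0, against 19383 genes with at least 1 CPM in IP-Svi-0, 31 of 236 pseudogenes were near absent (13.1%, odds ratio 40.0, adjusted p = 4.9e-34). So were 2 of 114 NLR genes (adjusted p = 0.277) and 1 of 249 long non-coding RNA genes (odds ratio 0.752), so the latter showed no excess there. Neighbouring genes are not independent, so these p values may be too small. Families were not matched for CPM, and a gene with few counts reaches no count more easily. Of the 284 genes near absent in IP-Svi-0, 104 had at least 5 CPM in Col-0, and of the 103 in Col-0, 15 had that in IP-Svi-0. Differences between families in CPM may therefore account for part of these excesses.

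Genes with at least 20 CPM in 1 accession and no count in at least 9 of the 12 libraries of the other were used to look for reads of the wrong accession. At 13 genes of IP-Svi-0, Col-0 16 °C replicate 3 had 14 counts at 8 genes, 4.91% of the mean of IP-Svi-0, and the other Col-0 libraries 0 to 0.754%. At 55 genes of Col-0, IP-Svi-0 16 °C replicate 3 had 18 counts at 9 genes, 0.375% of the mean of Col-0, and the other IP-Svi-0 libraries 0.0246 to 0.102%. At ESP, Col-0 16 °C replicate 3 had 138 counts, and the other Col-0 libraries 7 to 34. Whether this library held a small mixture of samples or exchanged indexes was not tested.

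Some counts came from a single library. ARP6 (opposite AT3G33530) had 6096 counts in Col-0 16 °C replicate 1 and at most 15 in any other library. PERK8 had 271 counts in Col-0 23 °C replicate 3, and AT1G29220 (opposite AT1G29200) had 540 in Col-0 10 °C replicate 1. The ribosomal RNA gene AT2G01010 had 402 counts in Col-0 10 °C replicate 2, 1154, 264 and 41 in Col-0 at 16 °C, and 112 in IP-Svi-0 16 °C replicate 3. Reads that did not align to a single place were 22.9 to 35.8% in Col-0 at 16 °C, 26.54% in Col-0 10 °C replicate 2 and 21.3% in IP-Svi-0 16 °C replicate 3.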
